A study of Arabidopsis thaliana with 12 samples.

How the data were processed

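Whole roots of Arabidopsis thaliana seedlings (ecotype Columbia) were profiled on 12 Affymetrix expression arrays, 1 array per sample. Per the labels' protocols, seedlings were grown on standard medium and moved to medium with 140 mM NaCl, and transfers were staggered so that every root was harvested within 3 h. Each replicate held about 15 roots, the RNA was amplified in 2 cycles per the labels' protocols, and the labels call the 2 samples of each group biological replicates. The groups were a control on standard medium and roots taken 30 min, 1 h, 4 h, 16 h and 32 h after transfer to salt. The control labels name no transfer, so salt and transfer were compared together. The labels give 5 days on standard medium for the control, 30 min, 1 h and 4 h samples. For the 16 h and 32 h samples the labels give both 4 and 5 days of growth before transfer, so these may differ from the control in earlier growth.

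The deposited values are linear signal intensities, 1 per probe set, made with MAS5 per the submitters' processing notes; its version and parameters are not given in the sources used here. A mean taken over each array without the lowest and highest 2 percent of its probe sets was 250.02 to 250.03 on all 12 arrays, so the arrays had been scaled to a common level before deposit. That scaling was kept. Detection calls were not used here. Precision is limited by the number of arrays, 2 per group.

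Of 22810 probe sets, 64 control probe sets were set aside. A probe set was kept where at least 2 of the 12 arrays exceeded their own 40th percentile, which left 14854. Values were analysed as log2(signal + 8.33), where 8.33 is the median over arrays of the 20th percentile of the signals, so fold changes are on the log2(signal + pseudocount) scale, which understates the change of genes with low signals. A group-means model was fitted over all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), so that the 6 groups shared an estimate of the spread. The residual degrees of freedom were 6 and the prior degrees of freedom 6.02. There were 10 contrasts: each salt time against control, each salt time against the one before, and 32 h against 1 h. A moderated F-test covered the 5 contrasts against control. All tests were two-sided, Benjamini-Hochberg adjustment was applied within each contrast, and a probe set was called at an adjusted p below 0.05. Every adjusted p given for a gene comes from this limma model. The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

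Gene names came from a table of the platform annotation and were updated through gene numbers against the TAIR10.1 gene table, in which 13436 of 13513 single-gene probe sets were found and no symbol changed. Among the tested probe sets, 8100 matched 1 gene, 288 matched several and 6466 were unlisted in the table, so they are unnamed here. Because of this, 45 of the 409 genes in the 29 lists fixed beforehand had a probe set of their own, and 35 of them passed the filter. A list of ribosomal proteins to be drawn from gene descriptions was not used here because the tables hold no descriptions. Where a gene had several probe sets, the one with the highest mean over all arrays stood for it, which applied to 29 genes.

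The genes named were chosen by this rule. Against control, they are the 6 largest rises and the 6 largest falls among called probe sets matching exactly 1 gene, with both salt arrays beyond both control arrays, and up to 4 called members per list. Between salt times, they are the 4 largest rises and 4 largest falls by the same rule. Lists with at least 4 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the lists and the 5 times. Gene families of at least 6 tested members, defined by symbol or by the chloroplast genome, were added after the data were seen and were tested in the same way as a set of their own.

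Every contrast against control used the same 2 control arrays, so overlaps of calls were set beside the overlap of independent lists and beside 100 simulations of unchanged groups sharing those arrays. The pipeline was tested on simulated data for 1 h against control with 14854 probe sets: it recovered 98 percent of 100 probe sets changed 4-fold and 40 percent of 100 changed 2-fold, and 10 of its 148 calls were unchanged probe sets. Alternatives covered the pseudocount, the filter, the normalization between arrays, the variance prior, array weights, the replicate number as a block, fits of the 2 compared groups alone, a 2-fold minimum and leaving out each array in turn. Further treatments of 3 arrays that stood apart were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.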

Results

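Gene expression was measured in whole Arabidopsis roots without added salt and at 5 times up to 32 h after transfer to 140 mM NaCl, with 2 arrays for each of 6 groups. Within groups, replicate arrays correlated at 0.986 to 0.989 across probe sets at 30 min, 1 h and 32 h, and less closely in the control (0.96), at 4 h (0.939) and at 16 h (0.969). The first principal component held 32.4 percent of the variance and placed the control, 30 min and 1 h arrays on one side and the 4 h, 16 h and 32 h arrays on the other. Replicate 1 of the control stood apart in the probe set for 25S ribosomal RNA, with a signal of 5551 against 1425 to 3507 on the other 11 arrays. Its signal was also highest in a CreX control probe set (9146 against 4340 to 6107). The highest signal of any probe set was 16462 on that array against 8810.6 to 13790. On the second principal component it lay at 52.6, against -20.6 to 26.3. This array enters every contrast against control. Signals are given below as mean ± SD with n = 2 arrays, and fold changes with the SE of their log2 value. Where one of the 2 signals compared lay below the pseudocount of 8.33, the size of the change depends on that pseudocount, so log2 changes and their range over all alternatives are given there in place of folds. Across the course 2090 of 14854 probe sets (14.1 percent) changed at any time by the moderated F-test. Without replicate 1 or 2 of the 30 min group that count was 1326 and 1343, without those of the 1 h group 1378 and 1323, without those of the 32 h group 1379 and 1382, and without replicate 2 of the 4 h group 3630.

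The comparison at 30 min asks which transcripts respond first after transfer to salt, where effects of salt and of the transfer cannot be told apart. PUB19 (AT1G60190), a plant U-box E3 ubiquitin ligase, rose 17.7-fold, from a signal of 30 ± 11 in control roots to 676 ± 230 (log2 change 4.15, SE 0.35, adjusted p = 7.2e-05). CML38 (AT1G76650), a calmodulin-like calcium sensor and the measured member of the touch-inducible list, rose from 3.91 ± 1.8 to 109 ± 5.4 (log2 change 3.27, SE 0.28, adjusted p = 7.9e-05, 1.22 to 4.53 over all alternatives). Of 3 measured members of the list of rapid stress transcription factors, 2 rose: the zinc finger gene STZ (AT1G27730, also known as ZAT10) by 2.26 on the log2 scale (SE 0.34, adjusted p = 0.0039) and WRKY53 (AT4G23810) by 1.61 (SE 0.24, adjusted p = 0.0039). WRKY6 had a log2 change of 0.24 and an adjusted p of 0.7. Adjusted over the list alone, 2 rose. The STZ call was lost without replicate 1 of the control or of the 30 min group, and the WRKY53 call without the latter, with log2 changes of 1.71 to 2.67 and 1.05 to 1.72 over all alternatives.

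Other large rises at 30 min were AT1G15010 (log2 change 3.42, with 1.51 to 4.37 over all alternatives), AT4G29780 (3.38), AT5G10695 (3.23) and AT5G11070 (3.05). AT1G76240 had the largest fall among named genes, from 484 ± 100 to 72.7 ± 11, which is 6.04-fold (SE 0.27 on the log2 scale, adjusted p = 0.00031). AT2G17070, AT1G22330, AT5G62280, AT3G07000 and AT1G13670 fell, with log2 changes of -1.66 to -1.41. In the list of abscisic acid-responsive and late embryogenesis abundant (LEA) proteins, 2 of 5 measured members rose, LEA4-5 (AT5G06760; log2 change 1.8, SE 0.39, adjusted p = 0.035) and the dehydrin gene LTI30 (AT3G50970; 0.75, SE 0.16, adjusted p = 0.035), and 2 rose adjusted over the list alone. As a set this list was higher by camera (adjusted p = 0.0176), a call lost with an estimated correlation (adjusted p = 0.241). In the cell wall list, XTH19 (AT4G30290), a xyloglucan endotransglucosylase gene, fell 2.36-fold (adjusted p = 0.012), the other 4 of 5 members were not called, and 3 members fell adjusted over the list alone. The cell wall list was lower by camera (adjusted p = 0.0262, and adjusted p = 0.173 with an estimated correlation). The LEA4-5 call was lost without any single control, 30 min or 1 h array (log2 change 1 to 2.15 over all alternatives). The LTI30 call was lost without any array except replicate 2 of the control and those of 4 h (0.7 to 0.8). That of XTH19 was lost without replicate 1 of the control or either 30 min array (-1.51 to -0.97). Without replicate 2 of the control the camera adjusted p was 0.196 for the LEA list and 0.175 for the cell wall list, and without replicate 1 of the 30 min group 0.0696 for the LEA list. Among the falls, each of AT2G17070, AT1G22330, AT5G62280 and AT1G13670 was not called without either 30 min array and AT3G07000 without its replicate 2. Leaving out replicate 1 of the control ended the calls of AT2G17070, AT5G62280 and AT1G13670, and leaving out its replicate 2 that of AT5G62280. Over these genes and all alternatives the log2 changes were -2.13 to -0.53. By limma, 234 probe sets rose and 61 fell at 30 min, 295 in all. The count was 135 without replicate 1 of the control and 500 without its replicate 2, 87 and 107 without replicate 1 or 2 of the 30 min group, and 512 and 513 without replicate 1 or 2 of the 4 h group, whose arrays enter only the shared spread.

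At 1 h PUB19 reached 900 ± 29, 24.2-fold above control (SE 0.35 on the log2 scale, adjusted p = 1.8e-05), and CML38 112 ± 12 (log2 change 3.3, adjusted p = 3.5e-05, 1.25 to 4.57 over all alternatives). LEA4-5 rose 11.2-fold to 487 ± 62 (log2 change 3.49, SE 0.39, adjusted p = 0.00026) and AT3G02480 rose to 151 ± 16 (log2 change 3.43, adjusted p = 8e-05, 1.46 to 4.53 over all alternatives). AT5G17850, AT5G10695 and AT1G15010 rose by 3.64, 3.53 and 3.49 on the log2 scale, the last with 1.57 to 4.45 over all alternatives. STZ (log2 change 2.44, adjusted p = 0.0012) and WRKY53 (1.24, adjusted p = 0.01) had risen, 2 of 3 members of their list, and 3 rose adjusted over the list alone. The WRKY53 call was lost without either 1 h array (0.78 to 1.35 over all alternatives).

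Single measured members of other lists also rose at 1 h: BZIP60 (AT1G42990), a transcription factor gene of the unfolded protein response, 1.9-fold (adjusted p = 0.019), and AT5G38710, entered in the compatible solute list as proline dehydrogenase PRODH2, 2.26-fold (adjusted p = 0.019). In the cell wall list XTH19 (log2 change -1.36, adjusted p = 0.0038) and XTH18 (AT4G30280; -1.19, adjusted p = 0.0078) fell, and 3 of 5 members were not called, with the same 2 falls adjusted over the list alone. Camera placed the cell wall list lower (adjusted p = 0.03, and adjusted p = 0.173 with an estimated correlation) and the abscisic acid and LEA list higher, with 2 of 5 members called both over all probe sets and adjusted over the list alone (adjusted p = 0.00155, and adjusted p = 0.182 with an estimated correlation). The largest falls among named genes were AT1G76240 (log2 change -2.54), AT1G44050 (-2.26), AT1G61840 (-2.14, with -3.25 to -0.62 over all alternatives), XTH16 (AT3G23730; -2.07), AT1G10400 (-2.04) and the chloroplast gene psbN (-1.93). Without replicate 2 of the control the camera adjusted p was 0.175 for the cell wall list and 0.0542 for the LEA list, and without replicate 1 of the 1 h group 0.0703 for the cell wall list. The calls of BZIP60 (log2 change 0.85 to 1 over all alternatives) and AT5G38710 (0.66 to 1.33) were lost without replicate 1 of the control or either 1 h array. The XTH18 call (-1.39 to -0.89) was lost without either 1 h array. Those of XTH19 (-1.63 to -1.09) and AT1G10400 (-2.51 to -0.95) were lost without replicate 2 of the 1 h group, and that of AT1G10400 also without replicate 1 of the control. The psbN call (-2.57 to -0.65) was lost without any single control or 1 h array. By limma 508 probe sets rose and 214 fell, 722 in all. The total was 347 without replicate 1 of the control, 278 and 233 without replicate 1 or 2 of the 1 h group, and 1155 without either 4 h array. Between 30 min and 1 h, limma called 1 probe set, which has no gene name in the table used and was higher at 1 h. In that contrast 459 probe sets had an unadjusted p below 0.05, where chance gives 743 if all groups had the same spread. They differed in spread, with mean half-differences between replicates of 0.098 and 0.104 (log2) at 30 min and 1 h against 0.243 at 4 h. The low count therefore does not show that nothing changed between 30 min and 1 h. The count of 1 called probe set was 178 with array weights and 193 in a fit of those 4 arrays alone, and 0 without any single array of the 30 min, 1 h or 32 h groups. It was 2 without either control array, 5 without either 4 h array and 3 without either 16 h array.

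**Figure D1:**
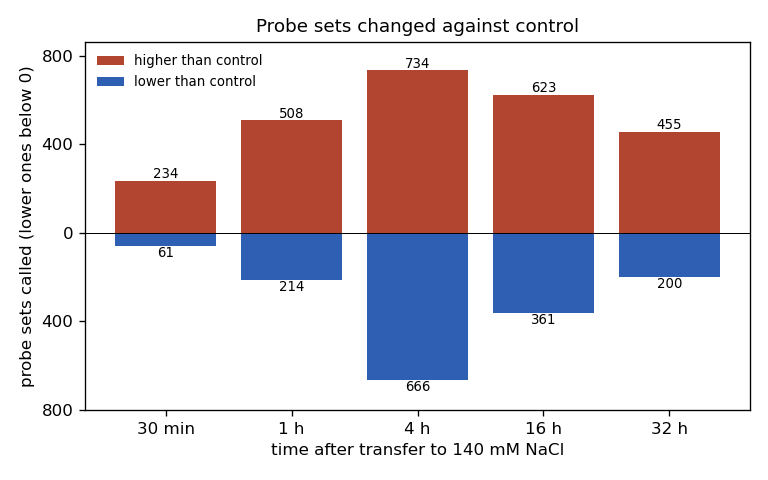
Number of probe sets higher (upward bars) or lower (downward bars) than control at each time after transfer, called with limma at an adjusted p below 0.05. The number of rises goes from 234 at 30 min to 734 at 4 h and 455 at 32 h, and the number of falls from 61 to 666 and 200. In fits of the compared groups alone the total at 4 h was below that at 16 h.

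At 4 h transcripts of LEA proteins rose steeply. COR15A (AT2G42540), a cold-regulated protein that protects chloroplast membranes, rose from 1.64 ± 0.28 to 715 ± 140 (log2 change 6.17, SE 0.65, adjusted p = 0.00012, 3.36 to 8.07 over all alternatives). LEA4-5 rose 67.7-fold to 2980 ± 550 (log2 change 6.08, SE 0.39, adjusted p = 2.7e-06), and AT3G02480 rose from 7.29 ± 7.1 to 2500 ± 1000 (log2 change 7.34, SE 0.33, adjusted p = 3.3e-07, 4.92 to 8.51 over all alternatives). All 5 measured members of the abscisic acid and LEA list rose, among them COR15B (AT2G42530; log2 change 3.22, adjusted p = 0.0011, 1.35 to 4.2 over all alternatives) and LTI30 (1.51, adjusted p = 0.00015), and COR47 by 0.79. The count was 5 adjusted over the list alone as well, with a median log2 change of 3.22. Camera gave the list an adjusted p of 2.1e-09, and an adjusted p = 0.0951 with an estimated correlation.

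AT3G15670 (log2 change 4.98, with 2.45 to 6.46 over all alternatives), AT3G17520 (4.91, with 2.65 to 5.98) and AT2G41190 (4.87) were the other large rises at 4 h. CML38 was still above control (log2 change 1.76, adjusted p = 0.0023, 0.46 to 2.83 over all alternatives), whereas none of the 3 rapid transcription factors was called, either over all probe sets or adjusted over the list alone; STZ had a log2 change of 0.9 (adjusted p = 0.13). The largest fall among named genes was that of AT2G41730 (from 1350 ± 210 to 121 ± 80, 11.7-fold, adjusted p = 0.00014, log2 change -4.22 to -2.87 over all alternatives). It was followed by AT3G12900 (log2 change -3.46), AT5G47980 (-3.31), AT5G01740 (-2.89), MSRB6 (AT4G04840, -2.71), which encodes a methionine sulfoxide reductase, and AT3G59340 (-2.66). AT3G12900 differed widely between replicates at 4 h (411 ± 540, adjusted p = 0.039), and its replicate 1 signal was also the lower one in the control and at 16 h. In the cell wall list XTH18 (log2 change -1.44, adjusted p = 0.0017) and COB (AT5G60920; -0.71, adjusted p = 0.042), needed for oriented cellulose deposition, fell, 3 of 5 were not called, and the list had a camera adjusted p of 0.157. Adjusted over the list alone, 3 members fell and 1 rose. The AT3G12900 call was lost without any single array except replicate 2 of the 4 h group and those of 16 h (log2 change -5.61 to -1.3 over all alternatives), and the COB call without any except replicate 1 of the control, replicate 2 of the 4 h group and those of 16 h (-0.89 to -0.54).

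By limma 734 probe sets rose and 666 fell at 4 h, 1400 in all, the highest count of the 5 times in this fit. That rank depends on the shared spread, since in fits of the compared groups alone the 16 h count was higher than the 4 h count. With array weights, which gave the 4 h arrays a weight of 0.34 against 1.7 to 2.09 for the 30 min, 1 h and 32 h arrays, the 4 h count was 437. It was 333 in a fit of the 4 h and control arrays alone, 902 without replicate 1 of the control and 2184 without replicate 2 of the 4 h group.

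From 1 h to 4 h, 387 probe sets rose and 548 fell. COR15A rose by 5.9 on the log2 scale (SE 0.65, adjusted p = 0.00042, 3.31 to 7.52 over all alternatives), AT3G02480 by 3.91, AT3G17520 by 3.68 and SAG29 (AT5G13170), a SWEET sugar transporter gene, by 3.48 (adjusted p = 9.2e-05). AT2G41730 (log2 change -4.01, adjusted p = 0.00018, -4.69 to -3.33 over all alternatives), AT3G12900 (-3.83) and AT5G51440 (-3.15) fell. So did GH3.3 (AT2G23170), which encodes an enzyme joining auxin to amino acids, with a log2 change of -3.47 (SE 0.86, adjusted p = 0.035), from 968 ± 20 to 95.1 ± 77. The calls of GH3.3 (log2 change -4.32 to -2.46 over all alternatives) and AT3G12900 (-5.98 to -1.67) were lost without any single 30 min, 1 h or 32 h array, and that of GH3.3 also without replicate 1 of the 4 h group. The total of 935 was 608 without the filter on low signals, 457 with array weights and 176 in a fit of those 4 arrays alone. It was 598 without either 30 min array, 245 and 171 without replicate 1 or 2 of the 1 h group, and 2432 without replicate 2 of the 4 h group.

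**Figure D2:**
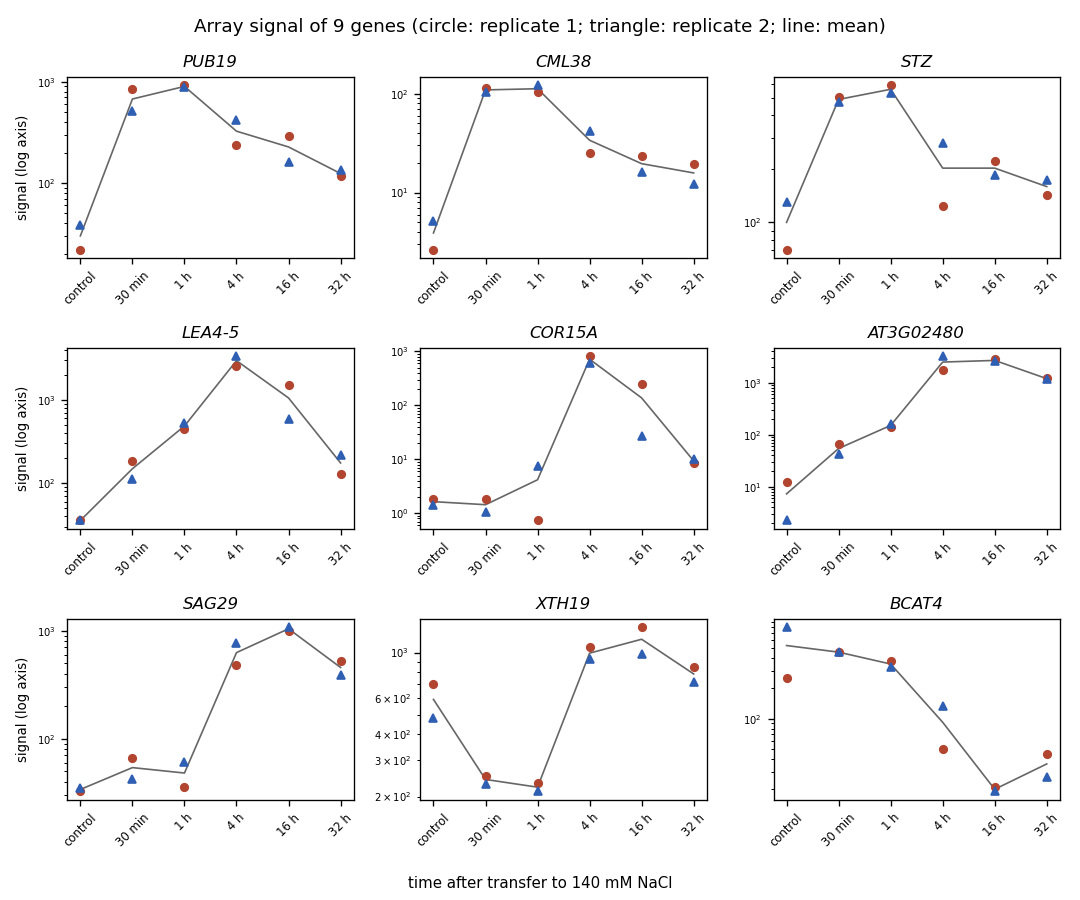
Array signal (log axis) of 9 named genes in control roots and at each time after transfer to 140 mM NaCl; circles are replicate 1, triangles replicate 2 and lines the mean of both. PUB19, CML38 and STZ are highest at 30 min and 1 h, COR15A and LEA4-5 at 4 h, and AT3G02480 and SAG29 at 16 h, while BCAT4 is lowest at 16 h.

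At 16 h AT3G02480 was above control (2690 ± 180, log2 change 7.51, SE 0.33, adjusted p = 2.5e-07, 5.08 to 8.68 over all alternatives). SAG29 had risen 24.7-fold, from 33.9 ± 1.7 to 1040 ± 68 (log2 change 4.63, SE 0.29, adjusted p = 3.3e-06), and AT2G37870 33.5-fold to 6940 ± 1000 (adjusted p = 2e-05, log2 change 4.13 to 5.85 over all alternatives). AT4G12580 (log2 change 4.84), AT5G50360 (4.66, with 2 to 6.84 over all alternatives) and LEA4-5 (4.46, adjusted p = 4e-05) were also among the largest rises. BCAT4 (AT3G19710), which encodes an aminotransferase of methionine chain elongation in glucosinolate synthesis, fell 16.2-fold, from 530 ± 390 to 20.1 ± 1.3 (log2 change -4.02, SE 0.48, adjusted p = 0.00041, -4.89 to -2.5 over all alternatives).

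Both measured root hair markers, the expansin genes EXPA7 (AT1G12560; 2.16-fold, adjusted p = 0.03) and EXPA18 (AT1G62980; 2.23-fold, adjusted p = 0.036), rose at 16 h, both over all probe sets and adjusted over the list alone. Their calls were lost without replicate 2 of the control or any single 30 min, 16 h or 32 h array, and that of EXPA18 also without either 1 h array, with log2 changes of 0.7 to 1.52 and 0.81 to 1.51 over all alternatives. XTH19, lower than control at 30 min and 1 h, was 1.95-fold higher at 16 h (adjusted p = 0.025), and CML38 remained higher (log2 change 1.19, adjusted p = 0.028). In the abscisic acid and LEA list 3 of 5 members rose, both over all probe sets and adjusted over the list alone, with COR15A at a log2 change of 3.25 (adjusted p = 0.012) and LTI30 at 1.31 (adjusted p = 0.00056). Camera gave it an adjusted p of 7.22e-06, and an adjusted p = 0.152 with an estimated correlation. GSTU25 (AT1G17180), a tau-class glutathione transferase gene, fell 1.91-fold (adjusted p = 0.0089). Other falls were AT3G12900 (log2 change -5.89), AT4G22212 (-3.92, adjusted p = 7.9e-06), AT1G73120 (-3.23), AT4G01390 (-3.08) and AT3G01260 (-3.06). The XTH19 call was lost without replicate 2 of the control or replicate 1 of the 16 h group (0.7 to 1.23 over all alternatives). The CML38 call was lost without replicate 1 of the control or any 30 min, 1 h or 16 h array (0.26 to 2.1). The COR15A call was lost without either control array (1.24 to 4.99) and the GSTU25 call without replicate 2 of the 16 h group (-1 to -0.89). Those of AT1G73120 (-3.58 to -2.79) and AT4G01390 (-4.83 to -1.33) were lost without either control array or replicate 1 of the 16 h group, and that of AT4G01390 also without any 30 min, 1 h or 32 h array. By limma 623 probe sets rose and 361 fell, 984 in all. The total was 443 in a fit of the 4 arrays compared, 575 without replicate 1 of the control, 513 and 447 without replicate 1 or 2 of the 16 h group, and 1577 and 1580 without replicate 1 or 2 of the 4 h group.

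From 4 h to 16 h, 165 probe sets rose and 64 fell. AT1G34510 rose by 3.94 on the log2 scale, from 48.9 ± 33 to 803 ± 170 (SE 0.35, adjusted p = 5e-04), followed by AT5G36270 (2.61), AT4G25790 (2.39) and AT5G06570 (2.22). COR15A (log2 change -2.91, SE 0.65, adjusted p = 0.05 after rounding), AT3G15670 (-2.89, adjusted p = 0.00077), AT4G22212 (-2.66) and COR15B (-2.31, adjusted p = 0.034) fell. The COR15A call was lost without any single array except replicate 2 of the 4 h group and replicate 1 of the 16 h group (log2 change -4.34 to -1.49 over all alternatives). The COR15B call was lost without any except those of the control and replicate 2 of the 4 h group (-3.17 to -1.14), and the AT5G06570 call without replicate 2 of the 16 h group (1.6 to 2.8). The total of 229 was 134 without the filter, 45 with array weights and 0 in a fit of those 4 arrays alone. It was 133 and 131 without replicate 1 or 2 of the 30 min group, 129 without either 1 h array, 135 and 134 without replicate 1 or 2 of the 32 h group, 71 without replicate 2 of the 16 h group and 1037 without replicate 2 of the 4 h group.

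At 32 h AT3G02480 was above control (1200 ± 43, log2 change 6.35, SE 0.33, adjusted p = 1.4e-06, 3.96 to 7.51 over all alternatives). AT2G37870 was higher 28.6-fold (5910 ± 740, adjusted p = 4.7e-05, log2 change 4.05 to 5.62 over all alternatives) and SAG29 10.9-fold (456 ± 97, adjusted p = 4.9e-05). AT5G07330 (log2 change 4.47, with 2.56 to 5.11 over all alternatives), AT5G04120 (4.29, with 2.73 to 4.7) and AT4G33550 (3.8) were the other large rises. PRODH2 (AT5G38710) rose 5.08-fold to 284 ± 19 (log2 change 2.34, SE 0.25, adjusted p = 0.00031). PRL (AT4G02060), which encodes a subunit of the MCM helicase that unwinds DNA for replication, fell 1.98-fold (adjusted p = 0.039). In the abscisic acid and LEA list 2 of 5 members rose, LEA4-5 4.04-fold (adjusted p = 0.013) and LTI30 1.81-fold (adjusted p = 0.012), with the same count adjusted over the list alone. Camera gave it an adjusted p of 0.00846, and an adjusted p = 0.241 with an estimated correlation. Without replicate 2 of the control its camera adjusted p was 0.132. The PRL call was lost without any single control, 30 min, 1 h or 32 h array (log2 change -1.18 to -0.71 over all alternatives), the LEA4-5 call without replicate 1 of the control or replicate 2 of the 32 h group (1.15 to 2.38) and the LTI30 call without either 32 h array (0.73 to 1.01).

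AT4G01390 (log2 change -4.64), AT3G12900 (-4.18), AT4G22212 (-3.94), BCAT4 (-3.42, adjusted p = 0.0017, -4.24 to -2.28 over all alternatives), AT3G01260 (-3.21) and AT2G19970 (-2.57) had the largest falls among named genes at 32 h. The AT4G01390 and AT3G12900 calls were lost without either 32 h array, and the latter also without either control array (log2 change -5.68 to -2.39 and -5.17 to -3.53 over all alternatives). By limma 455 probe sets rose and 200 fell, 655 in all. The total was 317 without replicate 1 of the control, 167 and 205 without replicate 1 or 2 of the 32 h group, and 1215 and 1213 without replicate 1 or 2 of the 4 h group. Between 16 h and 32 h limma called 9 probe sets, 7 higher and 2 lower, while 870 had an unadjusted p below 0.05 against 743 by chance if all groups had the same spread. The named ones were GAT1_2.1 (AT1G15040), a glutamine amidotransferase gene, which rose 7.73-fold from 70.4 ± 6.2 to 601 ± 48 (SE 0.42 on the log2 scale, adjusted p = 0.036), and AT4G12580, which fell 4.45-fold (adjusted p = 0.04). Both calls were lost without any single 30 min, 1 h, 16 h or 32 h array, with log2 changes of 2.22 to 3.07 and -2.52 to -1.79 over all alternatives. That count of 9 was 41 with the larger pseudocount, 67 with array weights, 0 without either 32 h array, 2 without either 1 h array, 3 without either 30 min array, 20 without replicate 2 of the 16 h group and 30 without either 4 h array.

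The direct comparison of 32 h with 1 h separates early from late transcripts. AT5G04120 was 31.2-fold higher at 32 h (9.9 ± 2.6 to 559 ± 59, log2 difference 4.96, SE 0.34, adjusted p = 2.2e-05). Its 1 h signal lay close to the pseudocount, and its log2 difference was 2.9 to 5.7 over all alternatives. Also higher were AT5G07330 12.2-fold (log2 difference 2.31 to 3.92 over all alternatives), AT4G33550 10.6-fold, and AT1G48070 by 3.27 on the log2 scale (1.17 to 4.9 over all alternatives). AT4G01390 was lower (from 572 ± 61 to 5.84 ± 2, log2 difference -5.36, SE 0.8, adjusted p = 0.0016, -6.41 to -3 over all alternatives), as were AT3G12900 (-4.55), AT1G49570 (-4.01) and GH3.3 (-3.7, SE 0.86, adjusted p = 0.022). The calls of AT3G12900 (-4.93 to -3.89 over all alternatives), AT1G49570 (-4.28 to -2.82) and GH3.3 (-3.97 to -2.88) were lost without any single 1 h or 32 h array. By limma 516 probe sets were higher and 456 lower at 32 h. Of those that had risen at 1 h, 243 were lower at 32 h than at 1 h, and 24 of these were still called above control at 32 h. In turn 231 probe sets were above control at 32 h and higher than at 1 h. Both counts pick probe sets through the same 1 h or 32 h arrays that enter the direct comparison, which favours such differences. The total of 972 was 2796 with array weights and 2775 in a fit of those 4 arrays alone. It was 407 and 331 without replicate 1 or 2 of the 1 h group, and 382 and 349 without replicate 1 or 2 of the 32 h group.

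Calls made at neighbouring times overlapped. Of 234 probe sets up at 30 min, 222 were also up at 1 h, where independent lists would share 8, and 57 were up at 32 h, against 7.2. At 16 h and 32 h 311 rises and 144 falls were shared, against 19.1 and 4.9 for independent lists. At 4 h and 16 h these were 391 rises and 205 falls, against 30.8 and 16.2. At 1 h and 4 h they were 241 rises and 85 falls, against 25.1 and 9.6. Simulated unchanged groups sharing the control arrays gave 0 to 0.02 shared calls. Groups without changes yield almost no calls at all, so this does not show how far the shared arrays raise the overlap of real calls. Across probe sets, which are not independent replicates, the fold changes at 30 min and 1 h correlated at 0.88 and those at 1 h and 32 h at 0.48, while the simulations gave 0.5. Their covariances were 0.207 and 0.137 against 0.038 in the simulations, differences of 0.169 and 0.099. The controls could not be split with 2 arrays left in each part, so part of the excess may come from the shared arrays. In all 1038 probe sets were called the same way at 2 or more times, 573 without replicate 1 of the control, 676 without replicate 2 of the 1 h group, and 1603 and 1608 without replicate 1 or 2 of the 4 h group. At all 5 times 44 were up, among them PUB19, LEA4-5, LTI30, AT3G02480, SRC2 and UGT87A2, and 10 were down, among them AT1G19900 and AT1G44050.

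Apart from the 4 reference genes, the remaining lists with measured genes held few and were described without a set test. No tested probe set was assigned to a single gene of the lists for abscisic acid receptors, clade A PP2Cs or abscisic acid synthesis. The same held for sodium and potassium transport, aquaporins, heat shock proteins, nutrient uptake and cytokinin. It also held for suberin, Casparian strip, xylem and root tip markers. The response of these genes is therefore unknown here. None of the 4 reference genes measured (UBC21, TIP41L, SAND and GAPC2) was called at any time, also adjusted over the list alone, and camera gave the list adjusted p values of 0.665 to 0.947. No member of the auxin list (GH3.3, LBD16 and GH3.5, listed as WES1) was called against control; adjusted over the list alone, 1 fell at 4 h, 1 rose at 16 h, and 1 rose and 2 fell at 32 h. The gibberellin receptor genes GID1A and GID1B, the ethylene regulator EIN3, the clock gene GI, the iron regulator PYE and the jasmonate synthesis gene OPCL1 were not called at any time over all probe sets. Adjusted over the list alone, OPCL1 fell at 4 h and 16 h and PYE rose at 1 h. The photosynthesis genes RCA and LHCB4.1, listed as markers of shoot tissue, were not called over all probe sets; adjusted over the list alone, 1 fell at 30 min, 1 h and 4 h and both rose at 32 h. Further changes passed adjusted over the list alone and not over all probe sets. By that count AT5G38710 was higher at 30 min, 4 h and 16 h, BZIP60 at 30 min, 1 rapid transcription factor at 16 h, and CML38 and both root hair markers at 32 h. PRL was lower at 4 h and 16 h and GSTU25 at 4 h and 32 h. In the cell wall list 2 members fell by that count at 16 h, and 1 rose and 1 fell at 32 h, where none was called over all probe sets. Camera gave adjusted p values of 0.947 and 0.927.

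Chloroplast-encoded genes, which include genes for ribosomal proteins and RNA polymerase subunits, and nuclear photosynthesis genes were examined as 2 sets. Both sets were put together after the data were seen, the nuclear one after RCA and LHCB4.1, and their checks by scaling and by left-out arrays were chosen after the medians over all arrays had been seen. The 49 chloroplast-encoded genes had median log2 differences from control of -0.27, -0.61, -0.56, -0.77 and -0.86 in order of time, with 0, 3, 7, 12 and 9 members lower and none higher. The control probe set for 25S ribosomal RNA had log2 differences of -0.02, -0.72, -0.57, -0.94 and -0.62, none called (adjusted p = 0.992, 0.447, 0.493, 0.257 and 0.481), on control signals of 5551 and 1919. Among the chloroplast genes rpl22 fell by 2.57 on the log2 scale at 16 h (adjusted p = 0.0062). Its control signal was 251 ± 210, so the size of that fall depends on the control array. The genes ycf4 (log2 change -1.71, adjusted p = 0.0088) and ndhJ (-1.94, adjusted p = 0.016) fell too. Their 16 h signals of 11.4 ± 6.7 and 10.5 ± 9.2 lay close to the pseudocount, on which the size of their change depends. Camera gave adjusted p values of 0.00756, 1.08e-07, 0.000342, 4.32e-11 and 1.83e-12, calls lost with an estimated correlation (adjusted p = 0.709, 0.516, 0.653, 0.415 and 0.382). The call at 30 min was also lost without replicate 1 of the control (adjusted p = 0.078) and with the stricter filter (adjusted p = 0.322). It was lost as well when the 3 arrays sharing a deviation (replicate 1 of the control, 4 h and 16 h groups) were left out (adjusted p = 0.0619) or marked by a covariate (adjusted p = 0.141), 2 settings chosen after the data were seen. At 32 h 2 members were lower without replicate 1 of the control, 0 without either 32 h array and 15 without either 4 h array, while the median stayed between -0.95 and -0.71. At 16 h there were 5 without replicate 1 of the control, 1 without replicate 2 of the 16 h group, 11 without its replicate 1 and 8 without replicate 2 of the control. The 16 h median was -1.21 without replicate 1 of the 16 h group and -0.52 without its replicate 2. At 1 h there were 0 without either 1 h array, 1 without replicate 1 of the control and 8 without either 4 h array. At 4 h there were 3 without replicate 1 of the 4 h group and 4 without replicate 2 of the control. The 17 nuclear genes had medians of -0.35, -0.29, -0.32, 0.45 and 0.7, with 3 members lower at 4 h, 1 higher at 16 h and 5 higher at 32 h. Without replicate 1 of the control the medians were -0.03, -0.09, -0.17, 0.56 and 0.84, and without its replicate 2 -0.47, -0.41, -0.6, 0.2 and 0.69. PSAN (AT5G64040), a photosystem I subunit gene, rose by 1.28 on the log2 scale at 32 h (SE 0.27, adjusted p = 0.021), and all 17 members had positive values at that time. Camera values for the nuclear set were adjusted over its own 5 times alone. Those for the chloroplast set were adjusted over all 110 family tests, so the 2 sets' adjusted p values are not comparable. The nuclear set includes RCA and LHCB4.1, which prompted it, so its tests are not independent of that choice. For the nuclear set camera gave adjusted p = 2.14e-09 at 32 h, and adjusted p = 0.0356 with an estimated correlation. It placed the nuclear set lower at 30 min, 1 h and 4 h (adjusted p = 0.00707, 0.0245 and 0.0201) and higher at 16 h (adjusted p = 0.00378), calls lost with an estimated correlation (adjusted p = 0.195, 0.2, 0.2 and 0.195). Without replicate 2 of the control or of the 32 h group 2 members were higher at 32 h, and without replicate 1 of the 32 h group 0. The single call at 16 h was lost without replicate 2 of the control or any 30 min, 1 h or 32 h array or replicate 2 of the 16 h group and became 2 without replicate 1 of the control or either 4 h array. The 3 at 4 h became 0 without replicate 1 of the control, 5 without its replicate 2 and 2 without any 30 min, 1 h or 32 h array. Between 1 h and 32 h 10 of the 17 nuclear genes were higher at the later time, and by limma 0 of the 49 chloroplast genes were called (median differences 1.21 and -0.22). No test compared the 2 sets with each other. The medians had the same sign at every time with quantile normalization and with arrays centred on their medians.

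**Figure D3:**
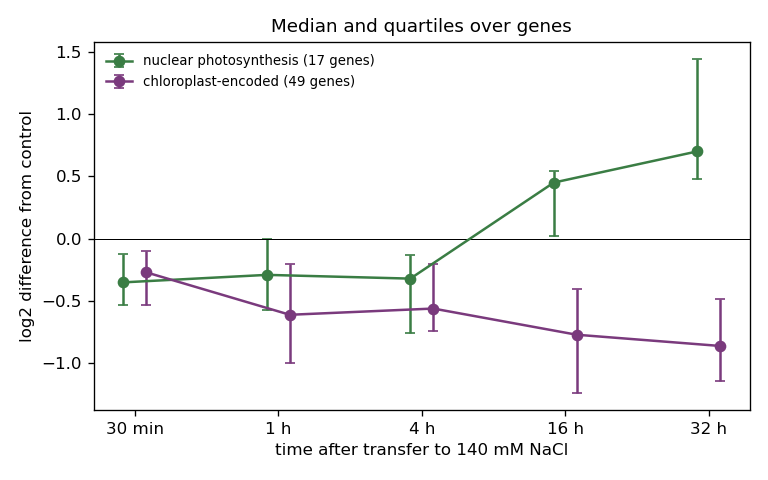
Median log2 difference from control (points) with the lower and upper quartiles over genes (bars) at each time after transfer to 140 mM NaCl, for 17 nuclear photosynthesis genes and 49 chloroplast-encoded genes. At 32 h the medians are 0.7 and -0.86.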

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

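The tests of RNA degradation, of a level-dependent scale difference, of green tissue, of RNA without a poly(A) tail and of the opposite calls without single arrays were chosen after the result was seen, and those of a single control array and of signal level after the chloroplast medians over all arrays were seen but before the values they gave.

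By limma 11 named genes were called above control at one time and below it at another. Their direct differences between those times all passed too, which the choice of genes brings about, so these add no evidence to the 2 calls. Each of the 11 lost a call without at least 1 array, and no change reversed its direction without any array; AT1G34510 kept both calls without 10 of the 12 arrays in turn, XTH19 without 9, and the other genes without 2 to 8. AT1G34510 was lower than control at 4 h (log2 change -1.51, adjusted p = 0.018) and higher at 16 h (2.43, adjusted p = 0.0017), a direct difference of 3.94 (adjusted p = 5e-04). AT2G32020 was higher at 1 h and lower at 4 h, with a direct log2 difference of -3.02, and AT3G28580 was higher at 30 min and lower at 16 h, with -2.77. The glycosyltransferase gene UGT88A1 (direct log2 difference 2.71), PSAN (2.57), AT3G32030 (2.51) and AT5G51110 (1.81) were lower at 4 h and higher at 32 h. XTH19 (2.32), AT5G24313 (2.31), AT5G54040 (1.86) and AT5G55050 (1.57) were lower at 1 h and higher at 16 h. Of these 11 genes, 5 changed at least 2-fold each way.

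Outside the tested probe sets, 1 of 64 control probe sets was above its control-group level at 1 h, that for the middle part of ubiquitin (log2 change 0.83, adjusted p = 0.0162), and by limma 0 were called at the other times.

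The replicate 1 arrays of the control, 4 h and 16 h groups differed from their replicate 2 arrays in a shared way, with replicate differences correlating across probe sets at 0.2 to 0.44 between these groups. AT3G28510 (mean log2 difference -2.74), ARPN (-2.31), OSM34 (-2.23) and GH3.3 (-2.03) were lower in replicate 1, and AT2G41810 (1.8) and GSTU28 (1.36) higher. A scale difference that follows signal level is argued against, since the mean correlation was 0.34 both as deposited and after quantile normalization, and the mean difference correlated with level at 0.03. RNA degradation stays open as a possible explanation. The 3' to 5' ratio was higher in replicate 1 in 4 of 9 pairs, actin going one way and ubiquitin the other. For ubiquitin these 3 arrays had ratios of 8.06, 8.56 and 6.74, against 3.5 to 5.3 on all other arrays. Actin was lower in replicate 1 in every group, also in those without the deviation, so it does not single out these arrays. GAPDH was higher in replicate 1 at 16 h and lower in the control and at 4 h. No biological explanation was tested.

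Of 49 chloroplast-encoded genes 0, 3, 7, 12 and 9 were called lower in order of time (0 at 32 h without either 32 h array), set calls by camera at the preset correlation were all lost with an estimated one (adjusted p = 0.382 to 0.709), and 5 of 17 nuclear photosynthesis genes were called higher at 32 h. A single control array is argued against, since the higher of the medians at 32 h without either control array was -0.71. So is a drift at that signal level, since 10000 random lists matched on mean signal had medians centred on -0.03, the lowest being -0.3. The median of -0.86 lay at percentile 0 of these lists. They ignore the correlation among chloroplast genes (estimated at 0.198), so that percentile does not measure the significance of the set's fall. Less green tissue in the salt samples would predict lower nuclear photosynthesis transcripts. Their median was 0.7 at 32 h, and their lowest median at 16 h without any single array was 0.2, opposite to that prediction. At 30 min, 1 h and 4 h their highest median without either control array was -0.03. The test cannot decide the amount of tissue, because these transcripts may themselves respond to the treatment, so less green tissue stays open at all 5 times. A lower share of RNA without a poly(A) tail stays open, because 25S ribosomal RNA differed from control by -0.62 at 32 h, and by 0.14 and -1.39 without replicate 1 or 2 of the control. The probe set for 5S ribosomal RNA differed by -0.2 at 32 h (limma adjusted p = 0.741). The control arrays had 25S signals of 5551 and 1919, while the mean of the chloroplast genes lay 0.02 and -0.02 from the control mean on the log2 scale. A lower yield of organelle RNA of every kind could not be tested, as 0 tested probe sets were listed as mitochondrion-encoded, and an effect of salt or of the transfer stays open and untested.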

How the results depend on the processing

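Leaving out, or marking with a covariate, 3 arrays that share a deviation was chosen after seeing the data, as were the families; the other alternatives were fixed before. Of 115 named gene results, 65 kept their direction and their call under every setting run for them, 50 lost the call under 1 or more and 0 reversed. Leaving out single arrays ended 43 of them; an arm left with 1 array takes the spread of the other groups. No tested gene among those named had another tested probe set, so the comparison with other probe sets of a gene gave no value. Other scalings moved the median of all probe sets by under 0.1. The cause of the shifts below was not tested, except that fewer arrays or more probe sets change the power by construction.

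With an estimated correlation 0 of 15 list tests were called. From 30 min to 1 h the count of 1 became 2 with a pseudocount of 1, 4 with a larger pseudocount, 0 without a filter and 0 with a stricter filter, 4 without the variance trend and 178 with array weights. From 16 h to 32 h the count of 9 became 5 with a pseudocount of 1, 41 with the larger one, 3 without a filter, 16 with median centring and 67 with array weights. Without a filter the counts were 608 from 1 h to 4 h and 134 from 4 h to 16 h. Array weights gave 437 at 4 h, 457 from 1 h to 4 h, 45 from 4 h to 16 h and 2796 from 1 h to 32 h. In fits of the compared groups alone the counts were 193 at 30 min, 333 at 4 h, 443 at 16 h, 193 from 30 min to 1 h, 176 from 1 h to 4 h, 0 from 4 h to 16 h and 2775 from 1 h to 32 h, and 588 probe sets were called the same way at 2 or more times. The replicate number as a block gave 5 from 30 min to 1 h and 15 from 16 h to 32 h and changed no named call; correlations of same-numbered deviations ranged from -0.21 to 0.44 and exceeded 0.1 in 4 of 15 pairs of groups, so the numbers were not taken to pair the samples throughout.

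Leaving out the 3 arrays gave 896, 1545, 3148, 2139 and 1986 probe sets at the 5 times, 174 from 30 min to 1 h, 2559 from 1 h to 4 h, 1275 from 4 h to 16 h, 229 from 16 h to 32 h, 3050 from 1 h to 32 h, 5138 at any time and 2494 called the same way at 2 or more times. As these arrays were picked for deviating, leaving them out lowers the estimated spread by selection. Marking them with a covariate gave 2401 at 4 h, 1829 at 16 h, 20 from 30 min to 1 h, 841 from 4 h to 16 h, 30 from 16 h to 32 h, 1664 from 1 h to 32 h and 1681 called the same way at 2 or more times.

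Without single arrays the counts ranged from 87 to 513 at 30 min, 233 to 1155 at 1 h, 902 to 2184 at 4 h, 447 to 1580 at 16 h and 167 to 1215 at 32 h. Between times they ranged from 0 to 5 from 30 min to 1 h, 171 to 2432 from 1 h to 4 h, 71 to 1037 from 4 h to 16 h, 0 to 30 from 16 h to 32 h and 331 to 1431 from 1 h to 32 h. At any time the range was 1323 to 3630, for calls shared by 2 or more times 573 to 1608, and for list calls 2 to 7, the lowest without replicate 2 of the control. Signals near the pseudocount limit what small changes of weak transcripts can show.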

Other observations

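The gene families below were defined after the data were seen, so all their tests were chosen after the result was seen. Of 110 family tests by camera 17 were called at the preset correlation and 0 with an estimated correlation. Of 9 SWEET sugar transporter genes, 4 rose and 1 fell at 4 h and at 16 h, and 3 rose and 1 fell at 32 h. SAG29 rose by 3.87 on the log2 scale at 4 h (adjusted p = 1.1e-05), SWEET13 by 2.38 at 16 h (adjusted p = 0.00051) and SWEET4 by 2.31 at 16 h (adjusted p = 0.0077), while SWEET16, a vacuolar transporter gene, fell by 1.69 at 4 h (adjusted p = 0.02). The family's camera adjusted p was 0.00756 at 4 h, 0.000695 at 16 h and 0.000946 at 32 h (adjusted p = 0.219, 0.168 and 0.168 with an estimated correlation). At 4 h the family median of 1.18 became -0.08 without the filter on low signals (adjusted p = 0.179), and without replicate 2 of the control the adjusted p was 0.0568; at 32 h it was 0.0567 without the filter.

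Of 6 xyloglucan endotransglucosylase (XTH) genes, 1 fell at 30 min and 3 at 1 h, with medians of -0.83 and -1.12 and camera adjusted p values of 0.00206 and 0.000695 (adjusted p = 0.168 at both times with an estimated correlation, and 0.174 with the stricter filter). Of 7 PUB genes, PUB19 rose at 30 min, and PUB19 and PUB24 at 1 h (camera adjusted p = 0.000836 and 0.000695, adjusted p = 0.168 at both with an estimated correlation). PUB23 fell by 2.05 at 16 h (adjusted p = 0.00053). No single member of the autophagy (ATG, 10 genes) or trichome birefringence-like (TBL, 17 genes) families was called by limma at 30 min or 1 h. As sets, ATG was higher (camera adjusted p = 0.0331 and 0.0103) and TBL lower (0.00638 and 0.00121), as was glycosyl hydrolase family 9 at 30 min (0.0268). With an estimated correlation these had adjusted p = 0.653 and 0.615, 0.516 and 0.48, and 0.415. Without replicate 1 of the control the adjusted p was 0.205 and 0.0712 for ATG, 0.271 and 0.102 for TBL and 0.185 for glycosyl hydrolase family 9. With the stricter filter the adjusted p at 30 min was 0.0718 for ATG, 0.069 for TBL and 0.174 for glycosyl hydrolase family 9, and without a filter 0.0629 for the last. Replicate 1 of the control, 4 h and 16 h groups share a deviation. With these 3 arrays marked by a covariate the adjusted p at 30 min was 0.179 for ATG, 0.0858 for TBL and 0.141 for glycosyl hydrolase family 9. With the 3 arrays left out it was 0.0707, 0.228 and 0.0905, and 0.0905 for TBL at 1 h. At 30 min it was 0.0628 for ATG and 0.056 for glycosyl hydrolase family 9 without replicate 2 of the control. It was 0.129 for ATG without replicate 1 of the 30 min group, and 0.069 for glycosyl hydrolase family 9 without its replicate 2.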
